A study of Mus musculus with 12 samples.

How the data were processed

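Poly(A) RNA from the left ventricle of 12 mice was sequenced in paired 150-nucleotide reads on a HiSeq X instrument, per the labels' protocols. The submitters' processing notes name bcl2fastq, TopHat2, edgeR and the genome build GRCm38, without versions or roles, and the counting tool, its annotation release and its strand setting are not given in the sources used here. The authors deposited a table of counts, whole reads per gene that are not normalised, for 25319 genes, each with an Ensembl identifier, a symbol and a gene type per the file headers. They also deposited a table of FPKM values, fragments scaled to gene length and library size, for 25258 of these genes, and the 61 genes absent from it had at most 2 reads in any library. Where FPKM was over 20 in every library (1424 genes), 100% of the values lay within 0.05 log2 units of the counts times a single factor per library and a length per gene, so the FPKM table holds the same measurement. Every gene row had a read in at least 1 library, 0 rows named no gene, and 0 columns of values were left without a sample. Since the strand setting is not given, a gene and an overlapping or antisense partner may not be told apart in these counts. Paralogs and pseudogenes may share reads.

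Samples were placed in their groups by their titles, 3 mice in each of 4 groups. Identifiers without their version were matched to GENCODE vM21 on GRCm38 for 25116 of 25319 genes, which gave coordinates and lengths (14911 of the genes tested). The processing notes name the same build.

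Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14965 genes and took out 0.0418% of the counts. Libraries were scaled by TMM, and all 12 libraries entered a single quasi-likelihood fit of 4 group means with robust dispersion estimates and 8 residual degrees of freedom. The comparisons were TAC control with sham control, TAC dantrolene with TAC control, sham dantrolene with sham control, TAC dantrolene with sham dantrolene, and the interaction. Tests were two-sided and p was adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. CPM values are counts scaled by the TMM-adjusted library total to the same size, and fold changes are given on the log2 scale with standard errors. With totals of 25766378 to 38363106 reads the spread between mice, a biological coefficient of variation of 0.443 common to all genes, enters every test beside counting noise.

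For groups of genes, 50 lists of pathways, cell type markers and index genes were written before the data were examined. Of these 48 were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, at least 5 tested members). Each call is given beside the test with the correlation estimated from the data, and beside fry, which asks whether a list's genes move on balance in 1 direction. A list's median is over the differences of its members' mean log2 CPM, while the counts of positive and negative members come from the fitted fold changes. Apart from Arntl, Dbp and the values per library of Hspa1a, and from list members named because they passed over their list alone, all picked after their values were seen, the genes named in the text follow a rule also written before the data were examined: genes passing the threshold with the largest changes, of which there were none; where a comparison called none, the 3 with the smallest p in each direction; 19 index genes; and up to 4 members of each list described, by smallest p. The result of 1 list member is not reported.

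The test was checked on simulated counts with the means, totals and spread of the real libraries and 200 changed genes. For the overload comparison it recovered 1.54% of the 2-fold, 45.5% of the 4-fold and 73.9% of the 8-fold changes among 14965 genes, and for the drug comparison under TAC 1.59%, 44.6% and 76.4%. With a low spread it recovered 88.9%, 100% and 98.6% for overload and 96.8%, 98.6% and 100% for the drug. When the matrix list was shifted by 1 log2 unit, camera called it with an estimated correlation (adjusted p = 2.7e-04) and called 0 other lists of 48 with the preset correlation. The simulated genes varied independently, so this does not check the preset correlation on lists whose genes vary together.

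Mice of a surgery arm that share a number deviated together. Across genes, the deviations of same-numbered control and dantrolene mice from their group means correlated with 0.465, 0.366 and 0.672 within sham and 0.556, 0.300 and 0.613 within TAC. Every such pair met the criterion of a correlation over 0.1 in both drug comparisons. Some mice of different numbers met it too. The values were 0.375 for sham dantrolene 1 with sham control 2, 0.305 for sham dantrolene 2 with sham control 1, and 0.221 for TAC dantrolene 3 with TAC control 2. The other pairs of different numbers within an arm lay below it, so the numbers may pair the mice but this is not shown. The labels state no reason for the pairing, and between sham and TAC several same-numbered mice correlated negatively. The number was therefore used as a block in an alternative fit of all 12 libraries. That block gives a number the same effect in sham and TAC mice, so it cannot remove in full what mice share within an arm.

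Alternatives written before the data were examined were the scaling of libraries by DESeq2 size factors and by upper quartiles, no filter and a filter on CPM of 1 in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, limma on log2 FPKM (pseudocounts 1 and 0.1), fits of the compared groups only, no robust estimation, the replicate block, stricter thresholds (0.01, and a log2 fold change of 1), and leaving out each library in turn. Chosen after the data were seen were fits without the libraries apart on the first principal component, with surrogate variables (sva 3.50.0), with the dependence of each library on gene length, with Arntl against Dbp, with library quality weights, and with the block in the compared groups only. Every alternative fit tried for the genes is reported. Figures were drawn with matplotlib 3.10.9.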

Results

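RNA sequencing was available from the left ventricle of 12 male C57BL/6 mice in 4 groups of 3. Mice were operated on at 8 weeks of age and sampled at 12 weeks. Transverse aortic constriction (TAC) narrows the aorta and loads the left ventricle with pressure, and the sham operation leaves the aorta open. In each arm 3 mice received dantrolene at 30 mg per kg per day for 4 weeks and 3 served as controls. Dantrolene binds ryanodine receptors, the calcium release channels of the sarcoplasmic reticulum, and the study asked about the RyR2 channel of the heart together with TNF-α, NF-κB and NLRP3 signalling. Total counts were 34488017, 27393064 and 25933503 in sham control mice 1 to 3 and 30067258, 29510446 and 25766378 in sham dantrolene mice 1 to 3. They were 30349124, 38363106 and 33798363 in TAC control mice 1 to 3 and 35021920, 37912351 and 28422879 in TAC dantrolene mice 1 to 3. Each library came from a separate mouse, and no pair of libraries of a group agreed within sampling noise, since the chi-square per gene between them was at least 31.7.

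Libraries of a group differed widely. The first principal component of the log2 counts scaled to library size (CPM) held 41.7% of the variance and set apart 1 library of each group, namely sham control 3, sham dantrolene 3, TAC control 1 and TAC dantrolene 1. Their scores ran from 34.7 to 85.6, against -50.7 to -22.7 in the remaining libraries. Mitochondrially encoded transcripts took 1.71% of the counts in TAC dantrolene 2 and 22.4% in TAC control 3, the extremes of the 12 libraries. The biological coefficient of variation common to all genes was 0.443. Xist stayed at or under 0.0421 CPM and the Y-linked Ddx3y at or above 2.80 CPM in every library.

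**Figure D1:**
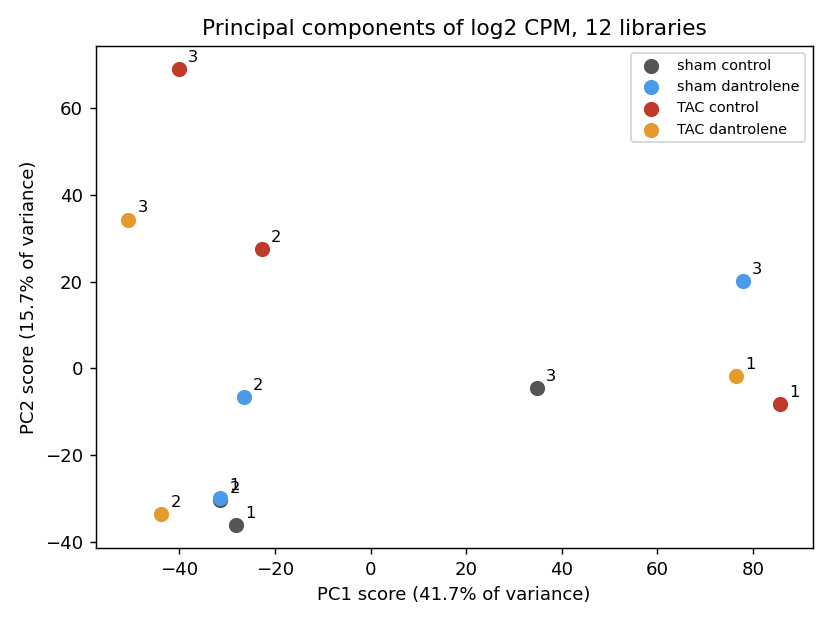
Scores of the 12 libraries on the first principal component (horizontal axis, 41.7% of the variance) and the second (vertical axis, 15.7%) of log2 CPM, with colours for the 4 groups and the mouse number beside each point. Sham control 3, sham dantrolene 3, TAC control 1 and TAC dantrolene 1 lie at 34.7 or higher on the horizontal axis and the other libraries at -22.7 or lower.

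The comparison of TAC control with sham control asked what pressure overload changed in mice without the drug. Acta1, skeletal α-actin, a sarcomeric gene of the fetal heart programme (ENSMUSG00000031972.4, chromosome 8, 123891769 to 123894751, minus strand), averaged 2403 ± 1422 CPM in TAC control and 283 ± 26.9 CPM in sham control (SD, n = 3), 8.49-fold higher. Nppa, which encodes atrial natriuretic peptide (ENSMUSG00000041616.9, chromosome 4, 148000722 to 148002079, plus strand), averaged 1491 ± 832 against 303 ± 152 CPM, and Nppb, which encodes brain natriuretic peptide, 1281 ± 349 against 349.5 ± 22.7 CPM. Postn, which encodes the matricellular protein periostin of activated fibroblasts (ENSMUSG00000027750.14, chromosome 3, 54361109 to 54391037, plus strand), was 9.10-fold higher, at 19.1 ± 14.9 against 2.11 ± 0.670 CPM. Leaving out 1 library at a time moved its log2 fold change of 3.19 between 2.54 and 3.68. Fmod, which encodes fibromodulin, a collagen-binding proteoglycan (ENSMUSG00000041559.7, chromosome 1, 134037254 to 134048277, plus strand), stood at 12.4 ± 3.71 against 0.696 ± 0.135 CPM. None of these differences passed the edgeR test across all genes. The DESeq2 Wald test called Fmod (adjusted p = 8.8e-11), Acta1 (adjusted p = 3.3e-07), Postn (adjusted p = 9.2e-04) and Nppa (adjusted p = 0.0102), and not Nppb (adjusted p = 0.171).

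Of 14965 genes tested with the quasi-likelihood test of edgeR, 0 had an adjusted p under 0.05 in this comparison. At an unadjusted p under 0.05 there were 1186 genes, 618 higher and 568 lower, where chance alone gives 748. The DESeq2 Wald test called 83 genes. The genes with the smallest p in the higher direction were Fmod (log2 fold change 4.14 ± 0.56 SE, adjusted p = 0.110), Ptgds, which encodes a prostaglandin D2 synthase (1.94 ± 0.31, adjusted p = 0.179), and Acta1 (3.09 ± 0.49, adjusted p = 0.179). In the lower direction they were Sorcs2, a sorting receptor (-2.21 ± 0.38, adjusted p = 0.233), Cacng6, a calcium channel subunit (-2.19 ± 0.38, adjusted p = 0.233), and Mrgprh (-1.79 ± 0.33, adjusted p = 0.237). Among 19 cardiac and inflammatory genes named in advance, 0 passed over all genes tested by edgeR and 5 had an unadjusted p under 0.05. Adjusted over the list alone, Nppa, Acta1 and Postn passed. Without the 4 libraries apart on the first principal component, a fit chosen after the data were seen that left 2 mice in each group, edgeR called 485 genes.

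Gene groups moved together in this comparison. All 39 tested genes of collagen and extracellular matrix had positive fold changes (median log2 0.52), with 2.96 ± 0.60 (SE) for Col12a1, a fibril-associated collagen, and 2.49 ± 0.65 for Lox, which crosslinks collagen. The list was called higher by camera (adjusted p = 2.4e-09), and had an adjusted p = 0.531 with an estimated correlation. Of 24 genes of activated fibroblasts 20 were positive (median 0.97), among them Cilp at 3.14 ± 0.66 and Thbs4 at 2.56 ± 0.56, with adjusted p = 4.6e-08 by camera and adjusted p = 0.417 with an estimated correlation. Of 15 genes of hypertrophy and the fetal programme 11 were positive (median 0.71, adjusted p = 0.0027, and adjusted p = 0.417 with an estimated correlation). Genes adjusted over the list alone numbered 5 in the matrix list, 13 in the fibroblast list, and 2, Acta1 and Nppa, in the hypertrophy list, all of them higher. No gene of these lists passed over all genes tested by edgeR.

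Immediate early genes, which answer acute stimuli, were lower in 17 of 20 members (median -1.69), with -2.26 ± 0.47 for Zfp36 and -4.01 ± 1.03 for Fosb (camera adjusted p = 2.5e-07, and adjusted p = 0.531 with an estimated correlation). Heat shock proteins were higher in 15 of 17 (median 0.55), with Hspa1a at 4.44 ± 1.12 and Dnaja1 at 2.16 ± 0.42 (adjusted p = 1.2e-05, and adjusted p = 0.417 with an estimated correlation). Hspa1a stood at 156 and 157 CPM in TAC control 2 and 3 and at 7.99 CPM in TAC control 1, against 4.27 to 5.89 CPM in sham control mice. All 15 mitochondrially encoded genes were positive (median 1.24, adjusted p = 8.5e-06, and adjusted p = 0.543 with an estimated correlation). All 8 markers of the epicardium and mesothelium, the cell layer on the heart's surface, were positive (median 1.89, adjusted p = 8.2e-04, and adjusted p = 0.417 with an estimated correlation), Msln at 5.05 ± 1.44 among them. The unfolded protein response (15 of 22 positive, adjusted p = 0.14) and oxidative stress (16 of 22, adjusted p = 0.095) were not called. Also called higher were complement (17 of 19 positive), macrophage markers (23 of 25), resting fibroblast markers (13 of 14), xenobiotic response (13 of 17), nuclear-encoded oxidative phosphorylation (40 of 49) and interferon response (22 of 26), with an adjusted p of 0.531 or higher with an estimated correlation. Called lower were potassium, sodium and gap junction channels (14 of 21 negative), with Kcnq1 at -1.04 ± 0.24, glycolysis and glucose transport (15 of 23) and fatty acid oxidation (18 of 25), with an adjusted p of 0.417 or higher with an estimated correlation. In all, 16 of 48 lists were called with the preset correlation, 12 higher and 4 lower, of which 9 were called in the same direction in every fit that left out 1 library. The 7 others were the macrophage, resting fibroblast, xenobiotic, oxidative phosphorylation, interferon, glycolysis and fatty acid oxidation lists. With the correlation estimated from the data camera called 0 lists, the smallest adjusted p being 0.417 and 5 lists having an unadjusted p under 0.05, and fry called 0, with 8 lists at an unadjusted p under 0.05.

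**Figure D2:**
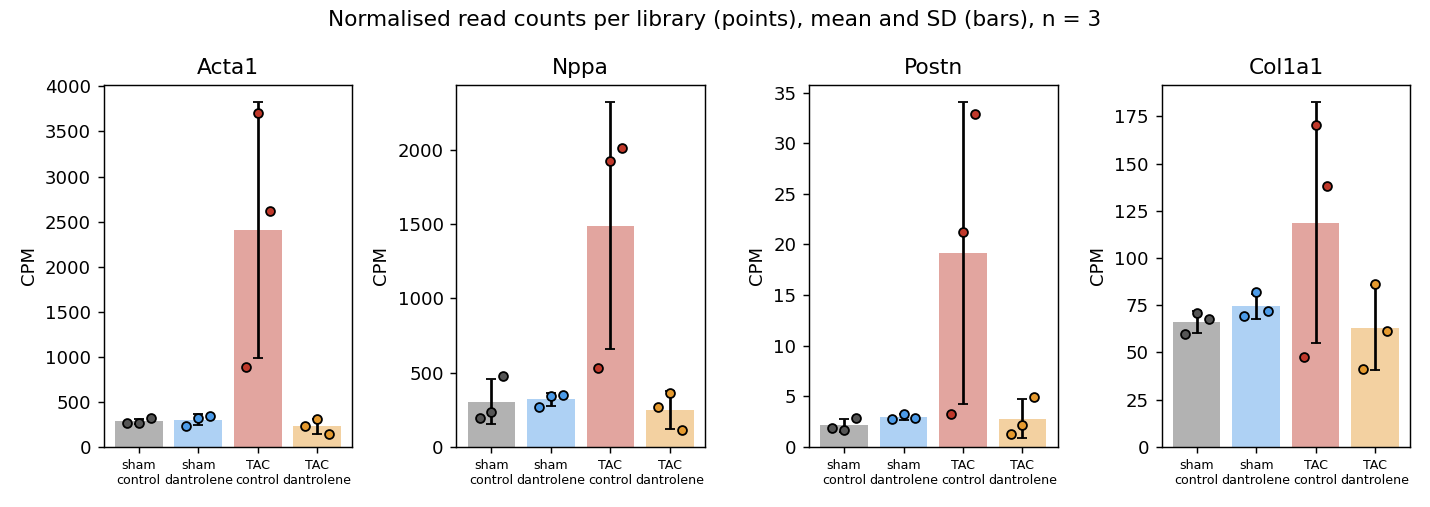
CPM of Acta1, Nppa, Postn and Col1a1 (vertical axes, starting at 0) in the 4 groups, with points for the 3 libraries of a group, bars for the mean and error bars for the SD. Acta1 averaged 2403 CPM in TAC control and between 229 and 299.8 CPM in the other 3 groups, and the 3 TAC control libraries spread from 887 to 3708 CPM.

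The comparison of TAC dantrolene with TAC control asked what the drug changed under pressure overload. Acta1 averaged 229 ± 82.8 CPM in TAC dantrolene (SD, n = 3), 10.5-fold lower than in TAC control, with every TAC dantrolene library (146 to 312 CPM) under every TAC control library (887 to 3708 CPM). Nppa averaged 247 ± 127 CPM, 6.04-fold lower, and Postn 2.78 ± 1.90 CPM, 6.88-fold lower. Leaving out 1 library at a time moved the log2 fold change of Postn between -3.47 and -2.14. Nppb differed by less than the spread between mice, at 1030 ± 1007 against 1281 ± 349 CPM. Col1a1, the main fibrillar collagen chain, averaged 63.0 ± 22.4 against 119 ± 63.8 CPM, and Myh6, the adult cardiac myosin heavy chain, 12240 ± 8143 against 5401 ± 1572 CPM.

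The quasi-likelihood test of edgeR called 0 of 14965 genes in this comparison, with 486 at an unadjusted p under 0.05 where chance alone gives 748, and DESeq2 called 12. With same-numbered mice paired in a fit of these 2 groups, chosen after the data were seen, edgeR again called 0, with 1016 at an unadjusted p under 0.05. The genes with the smallest p in the lower direction were Acta1 (log2 fold change -3.39 ± 0.50 SE, adjusted p = 0.245), Lman1l (-2.52 ± 0.52) and the pseudogene Gm10177 (-2.05 ± 0.43), whose reads could belong in part to its parent gene. In the higher direction they were Cacng6 (2.02 ± 0.38), Mrgprh (1.56 ± 0.33) and Sorcs2 (1.50 ± 0.37), and these 5 had an adjusted p of 1.00 by edgeR. Of the 19 genes named in advance 0 passed over all genes by edgeR and 6 had an unadjusted p under 0.05. Adjusted over the list alone, Nppa, Acta1 and Postn passed. The DESeq2 Wald test called the same genes over all genes: Acta1 (adjusted p = 4.9e-09), Nppa (adjusted p = 0.0073) and Postn (adjusted p = 0.022). Without the 4 libraries apart on the first principal component, a fit chosen after the data were seen, edgeR called 489 genes.

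Matrix and fibroblast genes were lower in TAC dantrolene as groups. Of 39 matrix genes 36 were negative (median log2 -0.45), with Fmod at -2.12 ± 0.51 (SE), Mfap4 at -1.60 ± 0.44 and Bgn at -1.19 ± 0.34 (camera adjusted p = 2.4e-11, and adjusted p = 0.395 with an estimated correlation). Of 24 activated fibroblast genes 19 were negative (median -1.19), with Cilp at -2.39 ± 0.63 (adjusted p = 1.7e-09, and adjusted p = 0.395 with an estimated correlation). The hypertrophy list had 10 of 15 members negative (median -0.25), Ankrd1 at -1.74 ± 0.56 among them (adjusted p = 0.0011, and adjusted p = 0.395 with an estimated correlation). Without TAC dantrolene 3 its adjusted p was 0.0581. Adjusted over the list alone, 4 matrix genes were lower, 10 fibroblast genes were lower and 1, Thbs1, was higher, and 3 hypertrophy genes, Acta1, Nppa and Ankrd1, were lower, while no member passed over all genes tested by edgeR.

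Interferon response genes were negative in 25 of 26 (median -0.70), with Ifit3 at -1.42 ± 0.41 (adjusted p = 1.6e-08, and adjusted p = 0.395 with an estimated correlation). Genes of MHC class II presentation were negative in 9 of 10 (median -0.88, adjusted p = 2.4e-04, and adjusted p = 0.442 with an estimated correlation), and macrophage markers in 21 of 25 (median -0.56, adjusted p = 4.1e-04, and adjusted p = 0.511 with an estimated correlation). Neutrophil (5 of 7 positive, adjusted p = 0.84), mast cell (6 of 7 positive, adjusted p = 0.84) and B cell markers (7 of 9 negative, adjusted p = 0.072) were not called. T and NK cell markers (10 of 13 negative), chemokines (13 of 22), complement (16 of 19), cell cycle (16 of 20), endothelial markers (13 of 18), resting fibroblast markers (12 of 14), heat shock proteins (14 of 17), oxidative stress (14 of 22) and nuclear-encoded oxidative phosphorylation (35 of 49) were called lower as well, with an adjusted p of 0.395 or higher with an estimated correlation. All 15 mitochondrially encoded genes were negative (median -1.64, adjusted p = 5.8e-10, and adjusted p = 0.425 with an estimated correlation). TAC dantrolene 2, the library with 1.71% of its counts from the mitochondrial genome, set the size of that difference: as a difference of group means of log2 CPM the median was -1.64 with it and -0.37 without it. Called higher were 7 lists: ion channels (17 of 21 positive, Kcnj5 at 1.23 ± 0.47), branched-chain amino acid catabolism (17 of 20), fatty acid oxidation (21 of 25), the tricarboxylic acid cycle (21 of 27), muscle ubiquitin ligases (7 of 10), calcineurin and MEF2 signalling (18 of 22) and immediate early genes (17 of 20), with an adjusted p of 0.395 or higher with an estimated correlation. In all 23 lists were called, 7 higher and 16 lower. Camera with an estimated correlation called 0, with 6 at an unadjusted p under 0.05, and fry called 0, with 5. Without TAC dantrolene 3 there were 7 lists, 0 higher and 7 lower, and without TAC control 1 there were 12, 1 higher and 11 lower. Matrix, activated fibroblast, interferon, mitochondrially encoded and heat shock genes, 5 of the 23 lists, were called lower in every fit that left out 1 library. Fits without a sham library kept every mouse of the 2 groups compared. The heat shock genes did not part the drug groups. Their mean log2 CPM was 6.93, 8.07 and 8.03 in TAC control 1 to 3 and 6.86, 6.99 and 7.62 in TAC dantrolene 1 to 3.

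The TNF and NF-κB list and the NLRP3 inflammasome list, which the study's question names, were not called. The 33 TNF and NF-κB genes had a median log2 difference of 0.04 between TAC dantrolene and TAC control (adjusted p = 0.94) and of -0.02 between TAC control and sham control (adjusted p = 0.58). The 16 inflammasome genes had medians of 0.06 (adjusted p = 0.42) and 0.04 (adjusted p = 0.86). Transcripts of the cytokines and of the sensor were scarce, with Tnf at 0.793 ± 0.0438, Il1b at 0.420 ± 0.20 and Nlrp3 at 0.299 ± 0.0101 CPM in TAC control (SD, n = 3), so these genes were measured from few reads. Casp1, the protease that the inflammasome activates, differed by -1.53 ± 0.70 (log2, SE, adjusted p = 1.00) between TAC dantrolene and TAC control, by -0.73 without TAC control 3 and by -2.40 without TAC dantrolene 3. Ryr2 itself averaged 197 ± 38.1 CPM in TAC control and 285 ± 95.9 CPM in TAC dantrolene, a difference of 0.53 ± 0.38 that did not pass. The 30 genes of calcium handling had medians of 0.06 in the overload comparison (adjusted p = 0.96) and 0.09 in the drug comparison (adjusted p = 0.49).

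The clock genes Arntl and Dbp and the heat shock gene Hspa1a parted the TAC libraries across the drug groups, and these genes were picked after their values were seen. Arntl, a transcription factor of the circadian clock, stood at 5.33, 6.28 and 8.52 CPM in TAC control 1, TAC dantrolene 1 and TAC dantrolene 2, and at 1.33, 1.79 and 0.877 CPM in TAC control 2, TAC control 3 and TAC dantrolene 3. Dbp, a clock output gene that peaks at the opposite phase, stood at 13.1, 31.6 and 17.5 CPM in the first 3 and at 184, 179.7 and 139 CPM in the others. Hspa1a, an inducible chaperone, stood at 7.99, 10.5 and 14.7 CPM in the first 3 and at 156, 157 and 129.6 CPM in the others. Of 17 heat shock genes 5 (29.4%) did not overlap between these sets of libraries, near the 25.9% of all genes tested. The clock list as a whole was not called by camera in TAC dantrolene against TAC control (median 0.16, adjusted p = 0.83) or in TAC control against sham control (median -0.24, adjusted p = 0.29). It holds genes of opposite phase, such as Arntl and Dbp, which offset each other in a test of 1 direction. The missing call therefore does not show that the clock was alike between the groups.

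**Figure D3:**
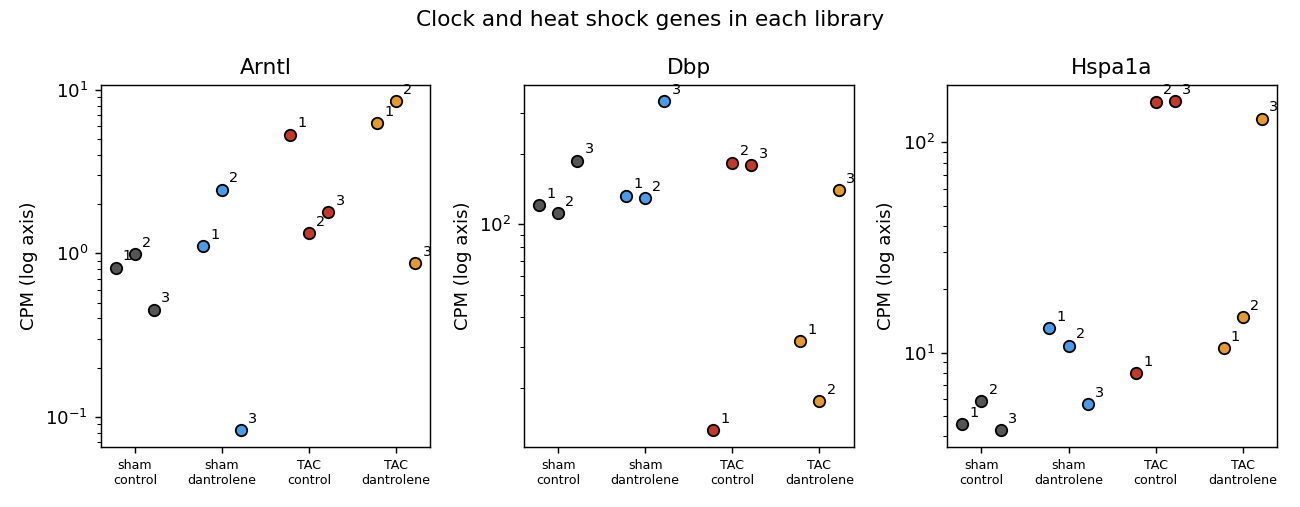
CPM of Arntl, Dbp and Hspa1a in each library (vertical axes, log scale), with colours for the 4 groups. TAC control 1, TAC dantrolene 1 and TAC dantrolene 2 have Arntl at 5.33 CPM or higher and Hspa1a at 14.7 CPM or lower, and the other TAC libraries have Arntl at 1.79 CPM or lower and Hspa1a at 129.6 CPM or higher.

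The comparison of sham dantrolene with sham control asked what the drug changed without overload. Acta1 averaged 299.8 ± 59.2 against 283 ± 26.9 CPM and Nppa 319 ± 45.6 against 303 ± 152 CPM, differences within the spread between mice. EdgeR called 0 genes, with 107 at an unadjusted p under 0.05 against 748 by chance, and DESeq2 called 0. With same-numbered mice paired in a fit of these 2 groups, chosen after the data were seen, edgeR called 0, with 1163 at an unadjusted p under 0.05. The genes with the smallest p, none of which passed, were Tfrc, the transferrin receptor (log2 -1.65 ± 0.41 SE), Plekhf1 (-1.12 ± 0.30) and Gm37033 (-3.53 ± 1.06) in the lower direction, and Atp7a, a copper transporter (2.38 ± 0.67), Bin2 (1.45 ± 0.47) and Grk5, a receptor kinase (0.79 ± 0.27), in the higher. None of the 19 genes named in advance had an unadjusted p under 0.05. Camera called 10 lists, and 0 with an estimated correlation (smallest adjusted p = 0.650). Cell cycle (16 of 20 positive, median 0.49), neutrophil markers (7 of 7, median 0.91, S100a9 at 3.03 ± 1.39), mitochondrially encoded genes (14 of 15), mesothelial markers (7 of 8), chemokines (17 of 22) and the unfolded protein response (17 of 22) were higher. Glycolysis and glucose transport (17 of 23 negative), muscle ubiquitin ligases (8 of 10), sarcomere (15 of 20, Ttn at -0.65 ± 0.51) and MHC class II (8 of 10) were lower. With an estimated correlation 3 lists had an unadjusted p under 0.05, and fry called 0, with 2. Without sham control 3 or sham dantrolene 3 the 10 lists were 6, none of the 10 was called in every fit that left out 1 library, and without the 4 libraries apart on the first principal component they were 4.

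The comparison of TAC dantrolene with sham dantrolene asked what overload changed in mice on the drug. Acta1 averaged 229 ± 82.8 against 299.8 ± 59.2 CPM (log2 -0.39 ± 0.46 SE), Nppa differed by -0.37 ± 0.54 and Postn by -0.08 ± 0.66. Immediate early genes were lower in 14 of 20 members (median -1.33, or -0.38 over the fitted fold changes), with Zfp36, an mRNA decay factor, at 58.2 ± 21.6 against 247 ± 78.5 CPM (SD, n = 3) and Ier2 at 87.7 ± 7.10 against 262 ± 119 CPM. EdgeR called 0 genes, with 256 at an unadjusted p under 0.05 against 748 by chance, and DESeq2 called 4, all lower. The genes with the smallest p were Usp18, an interferon-induced protease (-1.74 ± 0.37), Zfp36 (-2.09 ± 0.46) and Ier2 (-1.58 ± 0.36) in the lower direction, and Ppargc1a, a coactivator of mitochondrial genes (1.18 ± 0.32), Gabra3 (2.40 ± 0.66) and Cacfd1 (0.76 ± 0.21) in the higher, none of which passed in edgeR. The immediate early list was called lower (adjusted p = 1.1e-09, and adjusted p = 0.424 with an estimated correlation), and 5 of its genes, Zfp36, Ier2, Junb, Dusp1 and Ier3, were lower when adjusted over the list alone. Without TAC dantrolene 1 the immediate early genes had a median of -0.41 and were not called (adjusted p = 0.0727). T and NK cell markers (13 of 13 negative), B cell markers (8 of 9), chemokines (14 of 22), cell cycle (19 of 20), interferon response (21 of 26), MHC class II (8 of 10) and mitochondrially encoded genes (8 of 15, median -1.18) were also called lower, and mesothelial (7 of 8 positive) and smooth muscle markers (9 of 10) higher, with an adjusted p of 0.424 or higher with an estimated correlation. Matrix (median -0.01, adjusted p = 0.93), activated fibroblast (0.10, adjusted p = 0.50) and hypertrophy genes (0.04, adjusted p = 0.53) were not called. Without TAC dantrolene 2 the mitochondrially encoded genes were called higher instead, with a median of 0.35, so their lower call came from that library. Of the 10 lists 4, chemokines, T and NK cell markers, interferon response and cell cycle, were called lower in every fit that left out 1 library. Of the 10 camera called 0 with an estimated correlation, 3 having an unadjusted p under 0.05, and fry 0, with 1.

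The interaction of surgery and drug asked whether overload differed between mice with and without dantrolene. The overload response of Acta1, on the log2 scale, differed by -3.47 ± 0.66 (SE) in dantrolene mice from that in control mice. That of Nppa differed by -2.67 ± 0.78 and that of Postn by -3.27 ± 0.96. None of these passed over all genes tested by edgeR. These 3 genes passed when adjusted over the 19 genes named in advance alone. EdgeR called 0 genes for the interaction, with 422 at an unadjusted p under 0.05 against 748 by chance. The DESeq2 Wald test called 1, Acta1 (adjusted p = 0.0018). The genes with the smallest p were Acta1, Gm10177 (-2.48 ± 0.61) and Tceal7 (-4.24 ± 1.07) in the negative direction and Plekhf1 (2.15 ± 0.43), Sorcs2 (2.48 ± 0.52) and Cacfd1 (1.23 ± 0.30) in the positive. Matrix genes were negative in 35 of 39 (median -0.68, camera adjusted p = 1.9e-08, and adjusted p = 0.409 with an estimated correlation), activated fibroblast genes in 18 of 24 (median -1.27, adjusted p = 5.2e-06, and adjusted p = 0.409 with an estimated correlation) and hypertrophy genes in 9 of 15 (median -0.21, adjusted p = 0.025, and adjusted p = 0.409 with an estimated correlation). In all 21 lists were called, 6 positive and 15 negative. With an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05, and fry called 0, with 2.

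Set against each other, the overload and drug responses had opposite signs in most genes, as 2 comparisons sharing a group do without any effect. Of the 1186 genes with an unadjusted p under 0.05 in the overload comparison, 96.9% had the opposite sign in the drug comparison under TAC. Both comparisons contain the TAC control libraries, and groups of independent mice simulated without any effect gave 88.9%. The genes under that p in both with opposite sign numbered 285, against 149.8 in the simulated groups and 19.2 for independent lists. Over all genes the covariance of the log2 fold changes was -0.226, against -0.169 simulated, and the correlation -0.671, against -0.500. The 3 TAC control libraries are too few to be split, and the simulated mice lack the deviations that same-numbered mice share, so the excess over the simulated values is not shown to come from the drug. Genes called in both with opposite sign numbered 0 by edgeR and 11 of the 83 overload genes by DESeq2. The overload responses in control and in dantrolene mice, which share no library, correlated across genes with r = 0.204 and a slope of 0.171, and genes are not independent replicates. Simulated independent mice gave 0.00334, but same-numbered control and dantrolene mice deviate together, which by itself makes the responses correlate, so that value is not what no response would give. With the replicate block, which gives a number the same effect in both arms, the correlation was 0.112 and the slope 0.0843. Without sham control 3 the correlation was -0.00507, without TAC dantrolene 1 it was 0.0315, and without TAC dantrolene 2 it was 0.342.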

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

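All tests of explanations for the 3 patterns weighed below, and the bar for the second, which was moved between its 3 lists singly and its 77 genes together while the values were known, were chosen after the patterns were seen, and the expectations for the splits of the samples were written after the data were seen, while the test of the difference between the dantrolene responses was planned.

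The dantrolene response differed between TAC and sham mice in 21 gene lists by a test of the difference itself, camera with the preset correlation on the interaction of surgery and drug, and none of the 21 passed with an estimated correlation (adjusted p of 0.409 or higher). The median log2 difference was -2.38 for mitochondrially encoded genes, -1.27 for activated fibroblast genes, -0.93 for cell cycle, -0.92 for chemokines, -0.87 for interferon response, -0.78 for T and NK cell markers and -0.68 for collagen and extracellular matrix. It was -0.54 for macrophage markers, -0.46 for complement, -0.45 for heat shock proteins, -0.44 for nuclear-encoded oxidative phosphorylation, -0.44 for resting fibroblast markers, -0.33 for oxidative stress, -0.30 for the unfolded protein response and -0.21 for the hypertrophy list. It was 0.68 for muscle ubiquitin ligases, 0.57 for potassium, sodium and gap junction channels, 0.38 for calcineurin signalling, 0.36 for glycolysis, 0.31 for branched-chain amino acid catabolism and 0.29 for the tricarboxylic acid cycle. Fry called 0 of 48 lists with 2 at an unadjusted p under 0.05. Leaving out sham dantrolene 3 or TAC dantrolene 3 brought the 21 lists to 10, and leaving out TAC control 1 to 13. Without TAC dantrolene 2 the median for mitochondrially encoded genes was -0.79. In every fit that left out 1 library 6 of the 21 were called in the same direction: channels, matrix, activated fibroblast, interferon, mitochondrially encoded and glycolysis genes. Of 100 splits drawn, 6 gave as many lists, the highest other split giving 23, so chance is not excluded. All 100 splits gave as many genes as the 0 that edgeR called, as any split must (422 at an unadjusted p under 0.05, and 1 called by DESeq2). The highest other split gave 3221 genes.

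For each comparison of 3 mice with 3 there are 10 splits, too few for a share under 0.05. For TAC control against sham control the real split gave 16 lists, matched by 1 split, itself, with 12 in the highest other, and 0 genes by edgeR (1186 at an unadjusted p under 0.05, 83 by DESeq2), as did all 10 splits. For TAC dantrolene against TAC control it gave 23 lists, matched by 1 split, itself, with 15 in the highest other. It gave 0 genes (486 at an unadjusted p under 0.05, 12 by DESeq2), a number all 10 splits must reach, with 1017 in the highest other. Among the splits that part all 3 pairs of same-numbered TAC mice, those other than the real one gave 9, 12 and 15 lists and 0 genes by edgeR, and the splits that keep a pair together gave 4 to 13 lists, with the 1017 genes in 1 of them. For sham dantrolene against sham control 5 of 10 splits gave as many as the 10 lists, with 12 in the highest other (9, 8 and 9 where all 3 pairs are parted), and all 10 gave 0 genes by edgeR (107 at an unadjusted p under 0.05, 0 by DESeq2). For TAC dantrolene against sham dantrolene 5 of 10 gave as many as the 10 lists, with 14 in the highest other, and all 10 gave 0 genes by edgeR (256 at an unadjusted p under 0.05, 4 by DESeq2).

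The first pattern is the 4 libraries, 1 in each group, that lie apart on the first principal component with a gap of 57.5 to the others. After regression on the dependence of each library on gene length, the gap was -25.7, so the libraries no longer lay apart, and loss of long transcripts may account for it. That dependence comes from the same counts as the component (r = -0.887 between them), so the closed gap does not show the cause. Sham control 3, which lies apart, had a length slope of -0.0284, and sham control 1, which does not, had -0.0300. After regression on erythroid transcripts a gap of 25.4 was left, which does not decide whether blood in the tissue contributes. No biological explanation was tested, since the 4 libraries come from all 4 groups.

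The second pattern is the lower hypertrophy, activated fibroblast and matrix lists, 77 genes together, in TAC dantrolene than in TAC control (median log2 -0.49, camera p = 0.0314 with an estimated correlation, not a permutation p). With Arntl against Dbp in the fit the median was -0.43 (camera p = 0.0387, not a permutation p, and -0.90 to -0.28 leaving out 1 library). The lists were picked after they were seen to be lower in these libraries, so this unadjusted p does not decide on time of harvest. The term also covers only an effect that is linear in it. Among TAC libraries with high Arntl the median drug difference was 0.17, with 32 of 77 genes lower. Among those with low Arntl it was -0.92, with 66 of 77 lower. Each value rests on a single mouse on 1 side, but the lower median was not seen in both sets, so time of harvest is not excluded. With the length dependence of each library it was -0.60 (p = 0.0453, not a permutation p; -0.91 to -0.45), and with the dependence adjusted for GC content -0.58 (p = 0.0432; -1.10 to -0.50), which argues against loss of long transcripts as the whole cause. Taken singly, the matrix list went from -0.45 to -0.38 with the clock term and -0.56 with the length term, and the fibroblast list from -1.19 to -1.04 and -1.16, so the folds stayed about as large where camera's p no longer passed 0.05 (matrix with either term, fibroblast with the length term). Time of harvest, loss of long transcripts, the swap of labels weighed below, and an effect of the drug stay open.

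The third pattern is the parting of the 6 TAC libraries into TAC control 1, TAC dantrolene 1 and TAC dantrolene 2 against the rest, which gave 1017 genes and points to a structure of the samples. Of 14965 genes 3874 (25.9%) did not overlap between these sets and 712 (4.76%) did not overlap between the drug groups, where chance gives 10%. That 10% is the average over the 10 splits, and these sets were picked after the data were seen, so neither share is a test. Of 16 clock genes other than Arntl and Dbp 10 did not overlap between the sets and 0 did not overlap between the drug groups, but the sets were found from Arntl and Dbp, with which other clock genes are regulated, so the count does not decide and time of harvest cannot be told apart from other differences between the sets. Swapped labels of TAC control 1 and TAC dantrolene 3 cannot be told apart. TAC dantrolene 3 stood -0.92 from TAC control 2 and 3 over the 77 genes, beyond their spread of 0.38. TAC dantrolene 1 and 2 stood 0.17 from TAC control 1, and each value rests on a single mouse on 1 side. Acta1, a single gene, runs with the labels (887 CPM in TAC control 1, 146 CPM in TAC dantrolene 3). It had the smallest p between the groups as labelled, so it does not decide. Handling shared by mice of a number was not tested, and the sets hold numbers 1 and 3 together but divide number 2.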

How the results depend on the processing

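Of the alternatives below, the fits without libraries apart on the first principal component, with surrogate variables, with the length slope, with Arntl against Dbp, with quality weights, and with the block in the compared groups only were chosen after seeing the data. The cause of the differences between fits was not tested unless a sentence gives it.

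The count of 0 genes by edgeR was the same in all 5 comparisons with DESeq2 size factors or upper-quartile factors, with the CPM filter, limma-voom, log2 FPKM at either pseudocount, no robust estimation, and Arntl against Dbp as a term. Stricter thresholds on a fit that calls 0 can only give 0. The counts at an unadjusted p under 0.05 were 1186, 486, 107, 256 and 422. For TAC control against sham control there were 3 genes with no filter, 83 with DESeq2, 1 with only the 2 groups, 37, 137 and 56 with 1, 2 and 3 surrogate variables, 36 with the length slope, 4 with the slope adjusted for GC content, 485 without the 4 libraries apart on the first principal component, 1053 without the 3 farthest out, and 3262 with library quality weights. For TAC dantrolene against TAC control there were 1 with no filter, 12 with DESeq2, 2 with 3 surrogate variables, 489 and 241 without the 4 and the 3 libraries, and 65 with quality weights. For TAC dantrolene against sham dantrolene there were 4 with DESeq2 and 23 with 3 surrogate variables. For the interaction there were 1 with DESeq2, 3 with 3 surrogate variables, 7 and 10 without the 4 and the 3 libraries, and 68 with quality weights. For sham dantrolene against sham control every fit run gave 0, with 107 genes at an unadjusted p under 0.05 by edgeR and 0 called by DESeq2. The weights gave TAC control 2 a weight of 6.56, and the fits without libraries kept 2 or 3 mice per group.

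The replicate block in all 12 libraries, which gives a number the same effect in both arms, gave 0 genes by edgeR in all 5 comparisons and 17, 23, 11, 10 and 21 lists. Together with the length slope it gave 12 genes for TAC control against sham control, and 10 lists for TAC dantrolene against TAC control and 13 for the interaction. The block in only the 2 groups compared gave 0 genes in both drug comparisons, with 1016 (TAC) and 1163 (sham) at an unadjusted p under 0.05, against 460 and 111 with the block in all 12 libraries.

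Lists called fell to 0 in all 5 comparisons with an estimated correlation and to 0 with fry. With 3 surrogate variables there were 6 lists for TAC control against sham control, 9 for TAC dantrolene against TAC control, 5 for sham dantrolene against sham control and 13 for the interaction. The length slope gave 14 for TAC dantrolene against TAC control, and the slope adjusted for GC content 10 for TAC control against sham control, 7 for TAC dantrolene against TAC control and 10 for the interaction. For sham dantrolene against sham control there were 4 and 2 without the 4 and the 3 libraries, and 4 and 6 with 1 and 2 surrogate variables. With 1 surrogate variable the interaction had 13. The TNF and NF-κB and NLRP3 lists were called in 0 settings for TAC control against sham control or TAC dantrolene against TAC control.

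Leaving out 1 library at a time gave 0 to 14 genes for TAC control against sham control (1 without sham dantrolene 3 or TAC dantrolene 3) and 0 to 1 for TAC dantrolene against TAC control, both highest without TAC control 1, and 0 in the other 3. Lists ranged from 12 to 17, from 7 (without TAC dantrolene 3, and 12 without TAC control 1) to 24, from 6 (without sham control 3 or sham dantrolene 3) to 11, from 8 to 14, and from 10 (without sham dantrolene 3 or TAC dantrolene 3) to 24. Genes called in the overload comparison with an opposite call for the drug ranged from 0 to 1, and were 11 with DESeq2, 221 without the 4 libraries and 151 without the 3. The correlation of the overload responses ranged from -0.00507 (without sham control 3), a reversed sign, to 0.342 (without TAC dantrolene 2), and was 0.0315 without TAC dantrolene 1 and 0.112 with the replicate block. A log2 fold change of 1 or more gave no value for it.

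Of 4035 values of named genes under alternatives, 222 had the other sign, none of them called. What depth limits was not tested apart from the spread between mice.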

Other observations

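The values below belong to lists written before the data were examined that no comparison above describes in full, and no test was added for them. Erythroid transcripts, a measure of blood in the tissue, were positive in 6 of 6 members for TAC control against sham control (median log2 0.86, adjusted p = 0.32) and had a median of -1.0 for TAC dantrolene against TAC control (adjusted p = 0.0503), where 3 were positive and 3 negative and the median of the fitted fold changes was -0.03, neither of which passed. In sham mice Arntl ran from 0.0827 CPM in sham dantrolene 3 to 2.46 CPM in sham dantrolene 2, and Dbp stood at 335 CPM in sham dantrolene 3.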
